A study of Mus musculus with 6 samples.

How the data were processed

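Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open chromatin and adds sequencing adapters to the fragments, in 6 mouse liver samples labelled by the adenovirus used. The labels give 3 control samples with a virus for EGFP, a green fluorescent protein, and 3 samples with a virus for Dyrk1b, a kinase. The labels do not say that the replicates of a group were separate animals, so p-values measure the spread between these samples, which may be in part technical.

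The authors deposited 1 table of 22412 peaks, and per the file headers it gives read counts per peak and library and the RPKM values made from them. The deposited counts are whole reads over 1 merged peak set. No count is under 1 in any library, so an empty peak may have been entered as 1. The deposited RPKM values are the reads divided by peak length and by a library total that lies between 38.05 M and 48.3 M reads. Per the file headers the table also holds the log2 ratio of the mean RPKM values of the groups, a p-value and an FDR for each peak, all from the authors, and an annotation of each peak by gene and class. Peak names run to 30387, so the peaks in the file are part of a larger set, and the rest were not analysed here. The submitters' processing notes name Bowtie2, DiffBind and ChIPseeker with no versions. The peak caller, the handling of duplicate reads, any shift of reads for the transposase and the test behind the authors' p-values are not given in the sources used here.

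The same notes list the mouse build mm10. Gene positions in the table do not match it, since of 10558 gene names found on the same chromosome in a GRCm38 gene table, 3.38% started within 2 kb of their position there, and the median shift was 133 kb. Coordinates are therefore printed as deposited, for a build that is not named, and whether starts count from 0 or 1 is not stated. Gene symbols, exon and intron numbers are those of the deposited annotation. The GRCm38 table was used only to match older gene symbols and for this comparison.

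Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter, which left 22051 peaks and removed 361, and the quasi-likelihood test of Dyrk1b overexpression against control with no covariate. Peaks with a Benjamini-Hochberg adjusted p under 0.05 were called. Levels are TMM-normalised read counts scaled to the reads in peaks of a library (CPM), as mean ± SD over the 3 libraries of a group, and log2 changes are given with their standard error (SE). The common biological coefficient of variation was 19.9%. A peak counted as a promoter peak where the authors' class was promoter or its distance to the start of its own gene was at most 3 kb. Each of 28 gene lists, 19 for pathways and 9 for cell types, was fixed before the data were examined, as were the tests and part of the alternatives. Lists were tested on log2 CPM (prior count 2) with camera of limma 3.58.1, with 1 promoter peak per gene, the one with the highest mean, and a preset correlation of 0.01. Lists with at least 3 such genes entered, and p was adjusted over these lists. For 2 lists, glycogen and fatty acid oxidation, and for the 3 pathways of the closing section, all chosen after their values were seen, the median was set against random lists of genes. For the pathways this is not reported, since they had been picked for their high values. The rotation test fry and camera with an estimated correlation were alternatives. fry asks whether the genes of a list move, on balance, in 1 direction, or change in either direction, and does not compare the list with other genes.

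The genes named were set by a rule. It took every peak of Dyrk1b and Wbp2, and, since fewer than 20 peaks passed the threshold, the 8 peaks in each direction with the lowest unadjusted p whose groups did not overlap, 1 per gene, predicted genes left out. From each list it took up to 4 members with the lowest p, some of which are not reported here. The called peak at Gm38431, the list members Fads2, Fasn, Gys2 and G6pc, the single marker peaks of cell types and the pathways of the closing section fall outside it and were chosen after their values were seen.

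The same fit was tested on simulated counts with the means and library sizes of these peaks. At 22051 peaks it recovered 4.22% of changes of 1.5-fold, 36.1% of changes of 2-fold and 89.4% of changes of 4-fold, and 5.43% of its calls were false. Of 50 simulated lists of 15 genes shifted by 0.5 on the log2 scale, camera called 50, and of 50 unshifted lists it called 1. Simulated peaks varied independently, carried no trend with peak strength, and all genes of a shifted list moved alike. Each simulated peak took the fitted dispersion trend as its spread, with no variation of peaks around it. These rates therefore need not hold for the real peaks or lists.

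Reads in peaks came to 762633 to 1267934 per library. All pairs of libraries differed by more than sampling noise (chi-square per degree of freedom of 2.18 or more), so no pair was taken for 1 library deposited again, which does not show that they come from separate animals. Alternatives were other scalings, DESeq2 1.42.0, limma-trend, loess normalization against peak strength, other filters and thresholds, a replicate block, leaving out each library, autosomes or promoter peaks only, and other ways to set a gene's value. Log2 changes after loess normalization were fitted with limma-trend, so they differ from the main values by the test as well. The planned pseudocounts and the overlap of peak lists did not apply, because the table holds counts over 1 shared peak set. Figures were drawn with matplotlib 3.10.9.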

Results

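ATAC-seq libraries from 6 mouse liver samples were compared, 3 controls with an adenovirus for EGFP and 3 with adenoviral overexpression of Dyrk1b. The series title links hepatic Dyrk1b to glucose homeostasis through Wbp2, a coactivator that binds YAP and nuclear receptors, and the comparison asks how overexpression of the kinase alters open chromatin. Control libraries 1, 2 and 3 held 855787, 840463 and 762633 reads in the 22412 peaks, and Dyrk1b libraries 1, 2 and 3 held 768418, 891204 and 1267934. These were 1.89% to 2.22% of the library totals behind the RPKM values in controls and 1.67% to 2.63% in Dyrk1b libraries. Few of the reads thus lay in these peaks, which are part of a larger set, and how far this limited the calls was not tested. The median peak held 26 to 47 reads per library. A single exonic peak of the predicted gene Gm10800 (chromosome 2, 98496528 to 98497745) took 1.79% of the reads of control 1 and 2.94% to 5.3% of those of the other libraries.

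The first principal component of log2 CPM carried 32.6% of the variance and separated the groups, with controls at -44.42, -17.91 and -39.25 and Dyrk1b libraries at 38.82, 35.09 and 27.66. Across peaks, which are not independent replicates, Pearson correlations were 0.777 to 0.781 between control libraries, 0.703 to 0.812 between Dyrk1b libraries and 0.674 to 0.748 between groups.

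**Figure D1:**
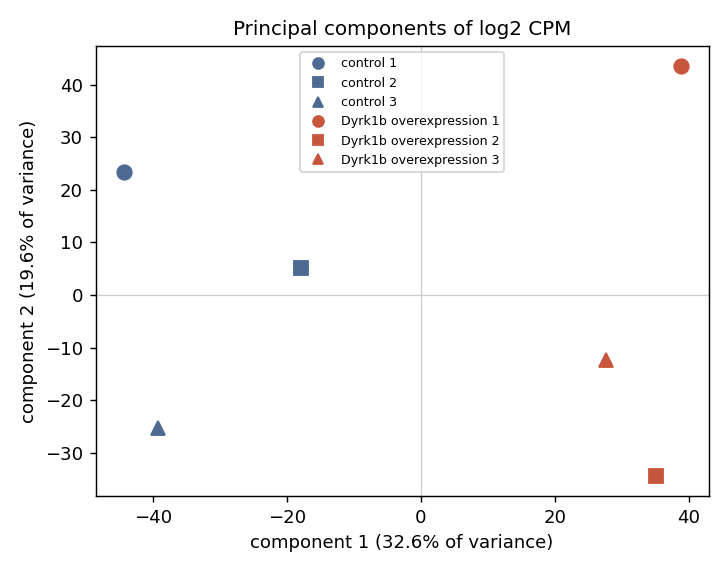
Scores of the 6 libraries on the first and second principal components of log2 CPM over the tested peaks, 1 point per library, blue for control and red for Dyrk1b overexpression. The first component, with 32.6% of the variance, places the controls at -44.42 to -17.91 and the Dyrk1b libraries at 27.66 to 38.82.

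The overexpressed gene gained reads at its own locus. The peak in exon 9 of 11 of Dyrk1b (chromosome 7, 27885143 to 27885495) rose from 5.63 ± 5.42 CPM in controls to 36.4 ± 3.84 CPM (SD, n = 3 per group), a log2 change of 2.64 ± 0.50 (SE). Its adjusted p was 0.00981 over all peaks by edgeR's quasi-likelihood test, and reads were 10, 1 and 3 against 27, 30 and 53. The call of the Dyrk1b exon 9 peak was lost without control 2 (log2 change 2.17, adjusted p = 0.114), control 3 (2.465, 0.0881) or Dyrk1b 3 (2.56, 0.167), and after loess normalization (2.16, 0.159) or with limma-trend (2.53, 0.0669), with adjusted p over all alternatives between 0.00296 and 0.167. The other Dyrk1b peak, in exon 11 of 11 (27885966 to 27886297), held 11.2 ± 0.804 CPM in controls and 34.7 ± 7.71 CPM with Dyrk1b, a log2 change of 1.61 ± 0.42. It did not pass over all peaks (adjusted p = 0.107) and passed adjusted over the list alone, the peaks of Dyrk1b and Wbp2 (adjusted p = 0.000421). A virus that carries the cDNA of the gene can add reads at its exons. The 15 other peaks within 300 kb had a median log2 change of -0.20, and 0 of them were called.

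At the Wbp2 promoter (chromosome 11, 115977819 to 115978877, 527 bases upstream of the start site) accessibility was 143 ± 60.4 CPM in controls and 87.3 ± 5.91 CPM with Dyrk1b, a log2 change of -0.72 ± 0.23. The peak did not pass over all peaks (adjusted p = 0.175 by edgeR's quasi-likelihood test). Adjusted over the list alone it had 0.00221, which is its unadjusted p. It had the highest p of that list, so the adjustment could not change it. Wbp2 was also chosen by the study, possibly on these samples, so the value over the list alone is not independent evidence. Control 1 held 208 CPM, against 88.3 and 133 CPM in controls 2 and 3, and the groups overlapped. Without control 1 the log2 change was -0.34, and without any other library it lay between -0.97 and -0.68. The authors' deposited table gives this peak a log2 ratio of -0.60 with an FDR of 0.552, and the exon 9 peak of Dyrk1b its lowest FDR, 0.0652.

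**Figure D2:**
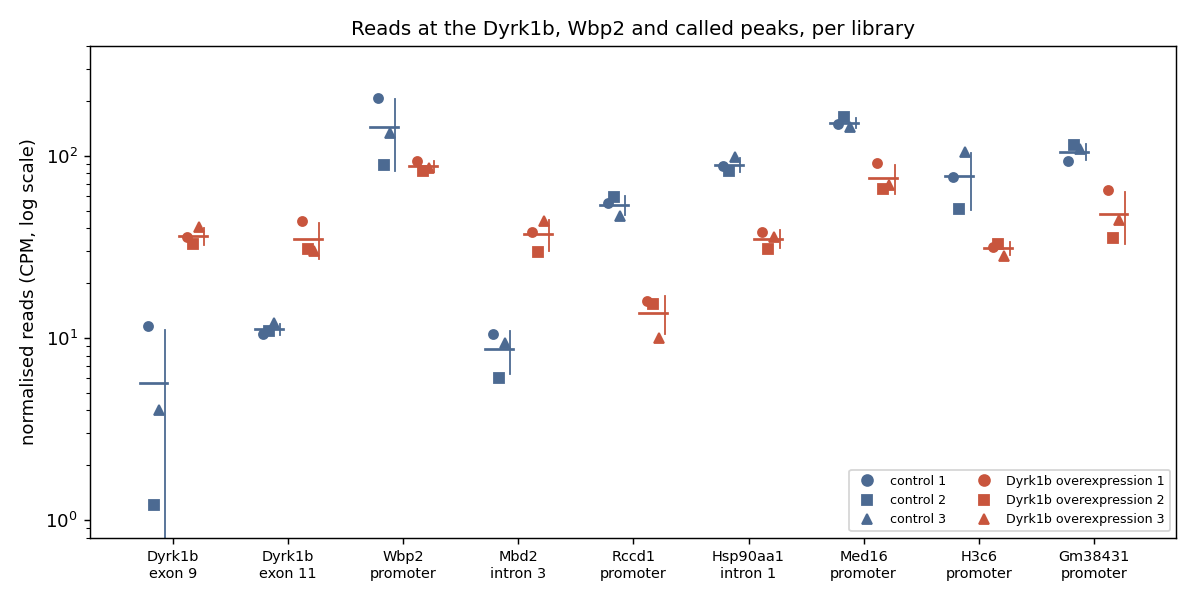
Normalised reads (CPM, log scale) per library at the Dyrk1b and Wbp2 peaks and the other called peaks. Points are libraries, horizontal lines group means and vertical lines 1 SD (n = 3), with the control SD at Dyrk1b exon 9 running off the lower end of the axis. At exon 9 controls lie between 1.21 and 11.7 CPM and Dyrk1b libraries between 32.9 and 40.5 CPM, and at the Wbp2 promoter control 1 stands at 208 CPM.

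Beyond Dyrk1b itself, 1 peak rose and 5 fell with overexpression. The peak that rose lay in intron 3 of 6 of Mbd2, a protein that binds methylated DNA (chromosome 18, 70743897 to 70744311), at 8.64 ± 2.32 CPM in controls and 37.2 ± 7.04 CPM with Dyrk1b (log2 change 2.10 ± 0.43, adjusted p = 0.0288). The deepest loss was at the start of Rccd1 (chromosome 7, 79973827 to 79974359), from 53.7 ± 6.29 to 13.7 ± 3.29 CPM (log2 change -1.998 ± 0.35, adjusted p = 0.00479). Accessibility also fell in intron 1 of 3 of Hsp90aa1, a cytosolic heat shock chaperone (chromosome 12, 110662603 to 110663392, log2 change -1.35 ± 0.25, adjusted p = 0.00981), and at the promoters of Med16, a subunit of the Mediator complex (chromosome 10, 79744074 to 79745291, -1.02 ± 0.21), and of the histone H3 gene H3c6 (chromosome 13, 23746633 to 23747619, -1.31 ± 0.27), each with an adjusted p of 0.0288. The remaining lower peak lay at the predicted gene Gm38431 (chromosome 9, 21002248 to 21003421, -1.15 ± 0.24), with the same adjusted p.

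In all, edgeR called 2 peaks higher and 5 lower among 22051 tested, each changed at least 2-fold and each with groups that did not overlap. DESeq2 called 0 higher and 18 lower, shared 4 calls with edgeR and gave no adjusted p for 16946 peaks, and the authors' deposited table has 0 peaks with an FDR under 0.05. At an unadjusted p under 0.05, 1419 peaks were higher and 1702 lower, 14.2% of those tested, where 1103 would be reached with no effect. The groups did not overlap at 4299 peaks, or 19.5%, where chance gives 10%. The counts of higher and lower calls were 1 and 2 without control 1, 0 and 3 without control 2, 0 and 1 without control 3, 1 and 9 without Dyrk1b 1, 6 and 1 without Dyrk1b 2, and 0 and 0 without Dyrk1b 3. With 1 library left out, the call at Rccd1 was lost without control 2 or Dyrk1b 3 and that at Hsp90aa1 without control 3, Dyrk1b 2 or Dyrk1b 3. Mbd2 stayed called only without Dyrk1b 2, Med16 and Gm38431 only without Dyrk1b 1, and H3c6 only without control 2. After loess normalization only Rccd1 stayed called, and with limma-trend only Rccd1 and Hsp90aa1. Scaling by library size only ended the calls at Med16, H3c6 and Gm38431. Scaled to the library totals behind the RPKM values, an alternative chosen after seeing the data that moved the median of all peaks by 0.17, 1 peak was higher and 0 lower, and of the peaks with p under 0.05, 13% were lower in place of 54.5%.

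Next by p among the genes the naming rule takes, none of them past the threshold by edgeR, were 6 genes with higher and 4 with lower accessibility. The higher peaks lay in introns of Dpf3, a subunit of the BAF chromatin remodelling complex (log2 change 1.996 ± 0.45), Ppfibp2 (1.52 ± 0.36), the transcription factor gene Sox5 (1.55 ± 0.37), Wipf2 (1.52 ± 0.37) and the ETS factor gene Etv5 (1.19 ± 0.29), and at the promoter of Grk2, a kinase of G protein-coupled receptors (1.61 ± 0.39). Their adjusted p ran from 0.0792 for Dpf3 to 0.105 for Etv5. The lower peaks lay in introns of Palmd (-1.28 ± 0.28, adjusted p = 0.0587), Svil, which encodes an actin-binding protein (-1.16 ± 0.27), and Irak2, a kinase of innate immune signalling (-1.11 ± 0.27), and downstream of the odorant receptor gene Olfr750 (-1.01 ± 0.24), the last 3 with an adjusted p of 0.0967. By DESeq2, Svil, Irak2 and Olfr750 did pass, each with an adjusted p of 0.0494, and the other peaks of this paragraph were given no adjusted p.

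The lowest p values among the metabolic lists were at the promoters of Plin2 and Srebf1, in the list for lipid synthesis. In the list for de novo lipogenesis and triglyceride synthesis, 10 of 15 promoter peaks had negative log2 changes, and 5 passed adjusted over the list alone, all lower: Plin2, a lipid droplet coat protein (-1.21 ± 0.29), Srebf1, the transcription factor that drives lipogenic genes (-0.97 ± 0.26), the ATP citrate lyase gene Acly (-0.78 ± 0.26), Dgat1, an enzyme of triglyceride synthesis (-0.77 ± 0.24), and the desaturase gene Fads2 (-0.68 ± 0.27). Plin2 went from 59.3 ± 12.3 to 25.7 ± 1.85 CPM and Srebf1 from 74.0 ± 21.8 to 37.97 ± 3.38 CPM. The fatty acid synthase gene Fasn had 0.41 ± 0.24. Over all peaks 0 of the 15 were called, with the lowest adjusted p at Plin2 (0.0967). The list had a median of -0.16 and an adjusted p of 0.434 by camera, and by fry it changed in either direction (adjusted p = 0.00221) but not in 1 direction (0.104). Without control 2 the first of these was 0.0619, and after loess normalization the median was -0.06. With 1 library left out, Acly stood at -0.44 (without control 1), Dgat1 at -0.505 and Fads2 at -0.41 (both without Dyrk1b 1) and Fasn at 0.19 (without control 2). In the same libraries 7 of 8 peaks at hepatocyte markers were negative (median -0.34) and 17 of 22 at markers of other liver cells positive (median 0.31). None of these marker peaks was called, and 1 of the hepatocyte ones had an unadjusted p under 0.05 by edgeR.

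Genes of glycogen metabolism moved in 1 direction by fry, the only such list with 1 promoter peak per gene and TMM normalization. Their promoters had a median log2 change of -0.22, with 8 of 11 negative (adjusted p = 0.0108 by fry). The lowest p were at Gbe1, the glycogen branching enzyme (-0.76 ± 0.21, from 179.5 ± 14.8 to 105 ± 19.2 CPM), and the phosphoglucomutase gene Pgm1 (-0.69 ± 0.23), which both passed adjusted over the list alone, followed by Gsk3a (-0.42 ± 0.21) and Ppp1r3c (-0.72 ± 0.37), which did not. The glycogen synthase gene Gys2 had -0.28 ± 0.26, and Gsk3a -0.21 without control 1. By camera, which compares a list with other genes, glycogen did not pass (adjusted p = 0.434, and 0.772 with an estimated correlation), and by fry it did not pass over all peaks of each gene (0.307), after loess normalization (0.0589, with a median of -0.09), without control 1 (0.0523) or control 2 (0.0979), or without Dyrk1b 1 (0.0807) or Dyrk1b 2 (0.0597). The median of all 7500 genes with a promoter peak was -0.07, and 1598 of 10000 random lists matched on size and mean reads had a median as low as that of glycogen. In the same libraries 7 of 8 peaks at hepatocyte markers were negative (median -0.34) and 17 of 22 at markers of other liver cells positive (median 0.31). None of these marker peaks was called.

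In the other lists of glucose handling 0 members passed over all peaks. Of 11 gluconeogenesis promoters 4 were positive. Pck2, the mitochondrial form of PEP carboxykinase, was higher (0.91 ± 0.27, from 35.9 ± 5.92 to 67.3 ± 5.46 CPM, adjusted p = 0.0116 over the list alone), while the glucocorticoid receptor gene Nr3c1 (0.68 ± 0.31), the transcription factor gene Klf15 (-0.46 ± 0.26), Pck1, the cytosolic form (-0.46 ± 0.28), and the glucose-6-phosphatase gene G6pc (-0.33 ± 0.26) did not pass. Among glycolysis and glucose uptake genes, 10 of 16 promoters were negative (median -0.21). Khk, the first enzyme of fructose breakdown, had -0.83 ± 0.26 (adjusted p = 0.0307 over the list alone), and Gapdh (-0.64 ± 0.24), the pyruvate dehydrogenase kinase gene Pdk2 (0.68 ± 0.30) and the glucose transporter gene Slc2a2 (-0.64 ± 0.31) did not pass. In insulin and mTOR signalling 16 of 22 promoters were negative (median -0.28) and 0 passed over the list alone. Rheb (-0.88 ± 0.32), Tsc1 (-0.77 ± 0.27), Trib1 (-0.69 ± 0.23) and the insulin receptor gene Insr (-0.68 ± 0.27) had the lowest p. With 1 library left out, Insr stood at -0.39 (without control 1), Nr3c1 at 0.34 (without Dyrk1b 2), Klf15 at -0.19 (without control 3) and Slc2a2 at -0.97 (without Dyrk1b 3).

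Further lists of hepatocyte metabolism gave similar counts. In cholesterol synthesis and uptake 8 of 11 promoters were negative (median -0.20), with Fdft1, which encodes squalene synthase, at -0.85 ± 0.25 (adjusted p = 0.0109 over the list alone). Fatty acid oxidation and ketogenesis had 15 of 20 negative (median -0.19, as low in 1031 of 10000 matched random lists), with Acaa2 at -0.59 ± 0.22 and Acaa1b at -0.62 ± 0.26, neither passing. Among xenobiotic metabolism genes 5 of 8 were negative (median -0.32), and Cyp3a11 (-0.86 ± 0.31) and Gstm1 (-0.59 ± 0.21) passed adjusted over the list alone. Cyp3a11 stood at -0.52 without Dyrk1b 2 and -1.415 without Dyrk1b 3, and loess normalization left Acaa2 at -0.38 and Gstm1 at -0.39. Bile acid synthesis and transport had a median of -0.07, with 4 of 7 negative and the bile acid receptor gene Nr1h4 at -0.70 ± 0.34. Nr1h4 also had the lowest p of the 7 hepatocyte transcription factors (median -0.15). Pericentral genes (4 of 7 negative, median -0.05) held Slc1a4 at -0.68 ± 0.22, which passed adjusted over the list alone, and periportal genes (4 of 8 negative, median -0.05) held Aldh1b1 at -0.81 ± 0.34.

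Lists outside metabolism had few members that stood apart. In Hippo, YAP and TAZ signalling (6 of 11 negative, median -0.01) only Wbp2 passed over the list alone (adjusted p = 0.0243), a gene the study chose, and Yap1 had -0.54 ± 0.31. The promoters of the DYRK kinase list (3 of 5 positive, median 0.11), which has no promoter peak of Dyrk1b, held Dyrk2 at -0.51 ± 0.23. Cell cycle genes were divided evenly (10 of 20 positive, median 0.02), with Lin9, a subunit of the DREAM complex that DYRK kinases regulate, at 0.82 ± 0.29 and the cyclin-dependent kinase inhibitor gene Cdkn1a at -0.67 ± 0.27. Medians were -0.33 for endoplasmic reticulum stress (Xbp1 at -0.62 ± 0.23), -0.23 for the circadian clock (Nr1d1 at -0.73 ± 0.26), -0.21 for inflammation and acute phase (Il6 at 0.77 ± 0.34, Crp at -0.77 ± 0.38) and -0.10 for the interferon response (Ifit2 at 0.44 ± 0.24), and 0 members of these 4 lists passed over the list alone. With 1 library left out, Yap1 stood at -0.20 (without control 1), Cdkn1a at -0.435 (without Dyrk1b 2), Ifit2 at 0.195 (without Dyrk1b 3) and Crp at -0.48 (without control 2).

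Over all 19 lists tested, 17 medians were negative, and 11 after loess normalization. The median of all 7500 genes with a promoter peak was itself -0.07, so a list need not stand apart to have a negative median. camera called 0, with adjusted p from 0.434 to 0.995, fry called 1 in 1 direction and 10 in either direction (0 without control 2, 1 without control 3 and 1 without Dyrk1b 3), and 14 members passed adjusted over their list alone. Median, mean and camera differed in sign for gluconeogenesis (median -0.11, mean 0.02, test up), DYRK kinases (median 0.11, mean -0.07, test up), and hepatocyte transcription factors, Hippo signalling and the interferon response (median and mean negative, test up). camera compares a list with other genes, and its unadjusted p for these lists was 0.484 to 0.995, so these directions carry little weight.

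**Figure D3:**
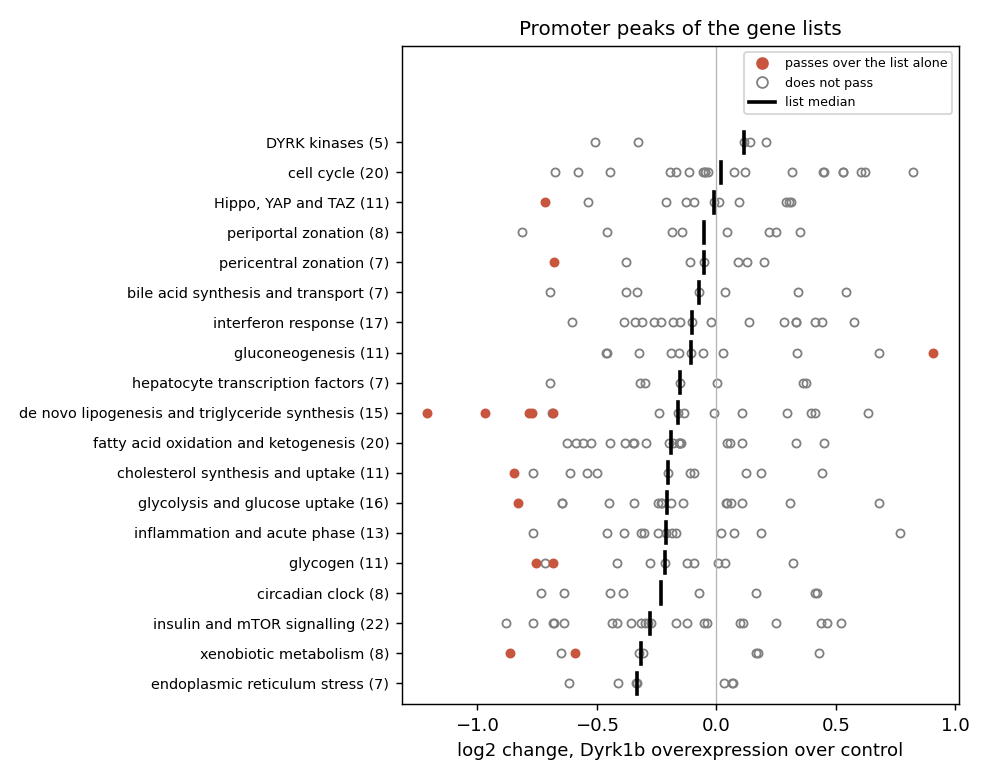
Log2 change (Dyrk1b overexpression over control) of the promoter peak of each gene in the 19 tested lists, with the number of genes in brackets. Each circle is a gene, filled where it passed adjusted over the list alone, and the black bar is the list median, from -0.33 for endoplasmic reticulum stress to 0.11 for DYRK kinases.

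Peaks at markers of liver cell types were examined in the same libraries, with no test of a difference between cell types. Of 8 peaks at 6 hepatocyte markers 7 had negative log2 changes (median -0.34), with Fgb, a fibrinogen chain gene, at -0.68 ± 0.32 and the albumin gene Alb at -0.11 ± 0.28, which turned to 0.45 without control 1 and 0.05 without Dyrk1b 1. Of 22 peaks at 18 markers of other liver cells 17 were positive (median 0.31), among them Ebf1 of B cells (1.37 ± 0.44), Csf1r of macrophages (0.67 ± 0.33) and Lrat of stellate cells (0.74 ± 0.48), while Spi1 of macrophages had a peak at -0.50 ± 0.21. The medians were 0.16 for macrophages (3 peaks), 0.52 for monocytes and neutrophils (1 peak) and -0.23 for T and NK cells (2 peaks). They were 0.97 for B cells (2 peaks), 0.31 for sinusoidal endothelium (8 peaks) and 0.14 for stellate cells and fibroblasts (3 peaks). Cholangiocytes had 0.62 (2 peaks) and erythroid cells 0.18 (1 peak). In each of these cell types, most listed markers had no peak. None of the marker peaks was called, and 5 in all had p under 0.05. With at most 2 promoter peaks per cell type, no marker list could be tested at promoters. Over all peaks of each gene 22 lists were tested, those of hepatocytes, sinusoidal endothelium and stellate cells included. None of these cell type lists passed by camera or fry. After loess normalization the medians were -0.20 at hepatocyte markers and 0.29 at the others, with Alb at 0.08 and Lrat at 0.38.

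Lower peaks lay at promoters more often than higher ones before, but not after, the trend with peak strength was removed. Promoter peaks, 43.4% of those tested, had a median log2 change of -0.07, and intronic peaks, 48.5%, one of 0.08. Of the called peaks, 4 of 5 lower and 0 of 2 higher were promoter peaks (2-sided Fisher's exact test, p = 0.143, the smallest these counts of peaks allow). Among peaks with an unadjusted p under 0.05, promoters made up 49.5% of the lower and 31.7% of the higher ones (Fisher's exact test, p = 5.59e-24, over peaks, which are not independent), and after loess normalization 38.1% and 44.7%, the reverse order.

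Weak peaks had higher and strong peaks lower relative accessibility in the Dyrk1b libraries. Over deciles of peak strength the median log2 change went from 0.40 in the weakest, where 16.7% were promoters, to -0.16 in the strongest, where 77.4% were. The difference between the weakest and the strongest decile, as each library's deviation from the mean of all, was -0.31, -0.03 and -0.18 in the controls and 0.35, 0.27 and 0.24 in the Dyrk1b libraries. Its group means differed by 0.46 (2-sided exact permutation test, p = 0.1, the smallest that 3 against 3 allow).

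**Figure D4:**
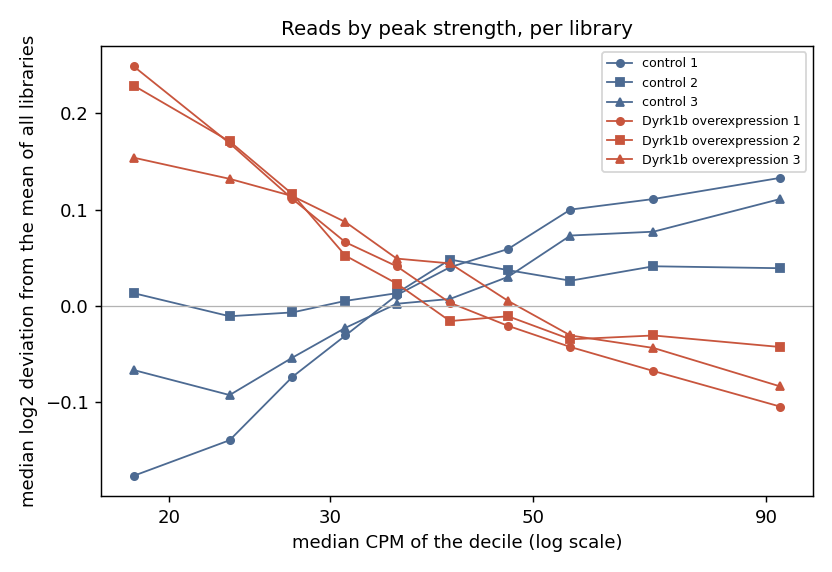
Median log2 deviation of each library from the mean of all 6, in 10 groups of peaks ordered by strength (median CPM of the group, log scale). The Dyrk1b libraries (red) start at 0.15 to 0.25 in the weakest peaks and end at -0.10 to -0.04 in the strongest, and the controls (blue) start at -0.18 to 0.01 and end at 0.04 to 0.13.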

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

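Full library totals, loess normalization of named peaks, lists and classes, filters and peak subsets at single peaks, limma-trend, DESeq2's test and the replicate block at the Dyrk1b and Wbp2 peaks, and removal of peaks over 500 CPM, which left 2 higher and 5 lower calls, were chosen after seeing the data. Under alternatives, 75 single peaks other than those of Dyrk1b and Wbp2 lost a call 43 times and gained one 8 times. Only the called peaks counted below could lose one. Many of the 75 peaks were picked for low p on the same counts, so a kept direction was close to given. Of 1273 values under alternatives, 1269 kept their direction. The 4 that reversed were at Alb, 0.082 after loess normalization, 0.048 with library totals behind the RPKM values, 0.452 without control 1 and 0.05 without Dyrk1b 1, where leaving out 1 library gave -0.404 to 0.452. Those totals also moved Dyrk2, G6pc, Gsk3a, Gys2, Klf15 and Spi1 by more than 1.5 times, with the same sign. Rccd1 stayed called in 13 of 16 alternatives, Hsp90aa1 in 12 of 17, Mbd2 in 7 of 15, and Med16, H3c6 and Gm38431 in 9 of 18 each. Higher and lower calls numbered 7 and 20 at an adjusted p under 0.1, 1419 and 1702 at an unadjusted p under 0.05, 0 and 18 with DESeq2, 0 and 1 after loess normalization, 0 and 2 with limma-trend, 1 and 4 over the 11206 strongest peaks, 0 and 4 over promoter peaks only, 2 and 2 by library size only, and 1 and 0 with the library totals behind the RPKM values. Leaving out 1 library gave 0 to 6 higher and 0 to 9 lower calls, from fewer samples. The Dyrk1b exon 9 peak was not called by limma-trend (2.53) or after loess normalization (2.16), and without 1 library its log2 change was 2.17 to 3.77, with the call lost without control 2, control 3 or Dyrk1b 3. Its adjusted p over the alternatives was 0.00296 to 0.167. The excess of promoters among lower peaks, 80 percentage points among called peaks, was 17.8 at an unadjusted p under 0.05, 17.9 there with promoters within 1 kb, and -6.63 after loess normalization, where it reversed. Camera called 0 lists under each planned setting and after loess normalization. fry, in 1 direction, called 1 with the settings of the report and with the mean of promoter peaks, 2 by library size only (glycogen, fatty acid oxidation), 2 over all peaks of each gene (fatty acid oxidation, cell cycle), 0 after loess normalization, and 0 or 1 without 1 library. Apart from the smaller samples and peak sets, the cause was not tested. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.01, -0.01 and 0.01, no library correlated best with its own number, and a replicate block left 2 higher and 5 lower calls and 0 lists by camera, while fry with the block called 0 in 1 or either direction, glycogen and lipogenesis included. The pseudocounts, the options for a table without counts and the overlap of peak lists could not be run. DESeq2 gave no adjusted p for Dyrk1b, Mbd2 or Rccd1. At this depth, spread and number of samples, simulated 1.5-fold changes were recovered in 4.22% of cases, and these limits were not told apart.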

Other observations

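The pathway test, the comparisons of exonic and neighbouring peaks, of weak and strong peaks and of the other splits of the libraries, and loess normalization at single peaks were chosen after the values they use had been seen, while leaving out each library at single peaks was planned.

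Among 301 KEGG pathways with at least 10 promoter peaks in the deposited annotation, 3 stood higher with Dyrk1b by camera. Glutamatergic synapse had 30 of 39 genes positive and a median log2 change of 0.28 (adjusted p = 0.00122), renin secretion 17 of 22 with 0.26 (0.0174) and calcium signaling 44 of 69 with 0.14 (0.0176). With an estimated correlation each had an adjusted p of 0.738. The lists share 14 to 15 genes pair by pair and hold 97 genes in all, so they are not independent of one another. Positive members with low p were Grk2 (1.61 ± 0.39), the calcineurin subunit gene Ppp3cc (0.84 ± 0.28), the endothelin gene Edn3 (1.41 ± 0.60), the phosphodiesterase gene Pde1c (1.53 ± 0.64), Fgf15 (1.12 ± 0.39) and the calcium channel gene Itpr2 (0.50 ± 0.22). Negative ones were the G protein subunit gene Gng12 (-0.69 ± 0.28), the calcium pump gene Atp2b4 (-0.77 ± 0.31) and the receptor kinase gene Met (-0.71 ± 0.30), and 0 members were called over all peaks. The peaks of Edn3 and Pde1c were weak. Edn3 went from 7.02 ± 1.89 CPM in controls to 18.65 ± 2.78 CPM with Dyrk1b, and Pde1c from 6.395 ± 4.9 to 18.67 ± 6.44 CPM. With 1 library left out, Fgf15 stood at 0.62 (without control 1), Pde1c at 2.32 (without control 3) and Atp2b4 at -0.36 (without Dyrk1b 3), and after loess normalization Pde1c at 0.89 and Edn3 at 0.75. In the same libraries 17 of 22 peaks at markers of liver cells other than hepatocytes were positive (median 0.31, and 0.29 after loess normalization), and 7 of 8 at hepatocyte markers negative (median -0.34). None of these marker peaks was called. The 3 pathways also passed after loess normalization (adjusted p of 0.00592, 0.00592 and 0.0435). Without control 1 no pathway passed (lowest adjusted p = 0.0594), without control 3 7 did, and without Dyrk1b 1 only glutamatergic synapse did.

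Reads were higher at both peaks of Dyrk1b with overexpression. A wider opening of the region is argued against by the 15 other peaks within 300 kb, whose median log2 change was -0.20. Reads from the viral cDNA are a candidate explanation, since 2 of 2 peaks lie in exons, as cDNA requires. An effect on the chromatin of these exons alone stays open, and reads that cross exon junctions, which would tell them apart, were not analysed here.

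The Wbp2 promoter was lower in the Dyrk1b group. The difference may rest in large part on control 1, since the log2 change was -0.34 without that library and -0.97 to -0.68 without each of the others. The trend with peak strength stays open as a partial explanation, since the change was -0.43 after loess normalization and -0.72 in the main fit. Both values come from the same counts, so the SE of 0.23 does not measure the uncertainty of their difference. The loess value was also fitted with limma-trend, which without loess normalization already gave a smaller loss than the main fit. Part of the shift therefore came with the change of test. A lower promoter accessibility caused by Dyrk1b also stays open.

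Weak peaks were higher and strong peaks lower in the Dyrk1b libraries. A smaller share of reads in peaks is argued against as the cause of the group difference. With peaks over 500 CPM left out, 2 of 3 Dyrk1b libraries had a larger share than every control (2.22% and 2.5% against at most 2.14%). These libraries also had a larger difference between weak and strong peaks than every control. Within each group, though, a smaller share went with a larger difference. Controls 1, 3 and 2 had shares of 2.14%, 1.85% and 1.76% with differences of -0.31, -0.18 and -0.03. Dyrk1b 3, 2 and 1 had shares of 2.5%, 2.22% and 1.53% with differences of 0.24, 0.27 and 0.35. The deepest library is argued against too, as the median fitted log2 change of the weakest decile minus that of the strongest, another measure than the values per library, was 0.545 without Dyrk1b 3 and 0.56 with it. How the peaks were called, read handling that differed between the groups and an effect of Dyrk1b on weak sites stay open, with no value here that bears on them.

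The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 7 called peaks and the highest other split 0. For peaks with p under 0.05 these were 3121 and 1086, for gene lists that moved in 1 direction by fry 1 and 0, and for KEGG pathways 3 and 1. In each case 1 split, the real one, reached the real value.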
